A study of Homo sapiens with 14 samples.

How the data were processed

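RNA from 14 prostate cancer xenograft arrays was compared. The titles give 7 xenografts, CWR22, LAPC4, LAPC9, LUCaP23, LUCaP35, LUCaP41 and LNCaP, each with 1 array in state HS and 1 in state HR. From knowledge of the study, HS was read as hormone-sensitive and HR as hormone-refractory growth, the series title naming the progression from HS to HR. LNCaP is an established human prostate cancer cell line, and the others are established xenograft lines kept in mice. With 1 array per xenograft and state, the spread between repeat tumours of 1 line was not measured, and the 7 xenografts served as replicates. The number of arrays limits the precision.

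The deposited values are probe set intensity on a linear scale in whole numbers, for 12626 probe sets including 67 controls, with values below 0 on every array. The 2% trimmed mean lay between 2502 and 2503 on every array, so the values had already been scaled by the authors before deposit, and they were kept as deposited. The software that made them is not stated in the sources used here. Gene names came from a probe table matched to the human RefSeq gene list, used for names only. In it 10961 probe sets had 1 gene symbol, 546 had several and 1070 had none.

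The test of each comparison, the gene lists, the rule for naming genes and most of the alternative settings were fixed before the data were examined. One part of that plan had to be changed. A floor under low values was planned at the 20th percentile of all values, but that value was -181, and the value at the 10th percentile was -768, so neither has a logarithm. The 35th percentile at 289 (8.17 on the log2 scale), which the plan held as another choice of floor, was used instead. Values below the floor were set to it and log2 was taken. A fold change of a probe set at the floor in 1 state is therefore measured against the floor.

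The control probe sets, and probe sets whose mean over the 14 arrays was under the 25th percentile of those means, were left out, which left 9419 tested probe sets. Of these, 8263 had 1 gene symbol, naming 6646 genes, and 1250 genes had more than 1 tested probe set. HR was compared with HS in limma 3.58.1 under R 4.3.3, with xenograft as a block, 6 residual degrees of freedom, moderated tests with an intensity trend, and Benjamini-Hochberg adjustment with a threshold of 0.05. Differences between xenografts were tested by the moderated F of the same fit over the xenograft terms. A count of probe sets that moved the same way in all 7 pairs, by at least 1.2-fold in each, used no variance model. Differences between 7 pairs outside limma were tested by exact two-sided sign flips, which can give no p below 0.0156. Plots were drawn with matplotlib 3.10.9 under Python 3.11.15.

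A set of 24 gene lists with 874 entries covered androgen response, steroid metabolism, the cell cycle, hypoxia, stress responses, growth signalling and cell type markers. The lines are kept in mice and the listed genes are human, so the marker lists cannot be read as amounts of host cells. Each list was tested with fry of limma on the brightest tested probe set per gene, with at least 5 genes per list. Its directional p asks whether the genes move one way on balance, and its mixed p whether they change in either direction; neither compares a list with other genes. Shares of each list past the xenograft threshold were compared with all other genes by Fisher's exact test.

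Genes were named by a fixed rule. Among probe sets past the threshold and moved the same way in at least 6 of 7 pairs, the 12 largest changes in each direction were to be named, and where fewer than 8 passed, places up to 8 were filled by smallest unadjusted p. In each list up to 4 members with the smallest unadjusted p were eligible, and KLK3, KLK2, TMPRSS2 and FKBP5 whatever their p. For the xenografts, the 10 genes with the largest F were named. A probe set with no gene or several genes was not named. The 2 planned results that rest on a single gene are not reported here.

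The match of HS and HR arrays to xenografts was checked by correlating each array's deviations from the mean of all arrays in its state. All 14 arrays correlated best with the array of the same name. The fit was tested on simulated data in 20 rounds, with 200 changed probe sets in each and each probe set's own residual spread. It recovered 36.7% of 2-fold and 83.6% of 4-fold changes, 3.44% of its calls were false, and it made 0 calls where nothing was changed. The changed probe sets were drawn only from those with a mean above the median of the tested values. The spread was the same on every array. Recovery nearer the floor, with fewer changed probe sets or with some arrays noisier than others was not simulated. Alternatives covered the block, quantile normalization, median scaling, a pseudocount, the filter, the variance model, array weights, a test without moderation, camera, and leaving out each xenograft in turn. Floors at the 30th and 50th percentile, and leaving out LAPC9 and LUCaP41 together, were added after seeing the data.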

Results

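Transcript levels were measured on 14 expression arrays from 7 prostate cancer xenografts, each with 1 array in the hormone-sensitive state, HS, and 1 in the hormone-refractory state, HR. Pairing by xenograft lets each HR tumour be compared with the HS tumour of the same line, and the question of the series was what changes as HS tumours become HR. The intensity was on a linear scale with values on both sides of 0, and 12 arrays had between 23.3% and 26.1% of probe sets at or below 0. The LAPC9 arrays stood apart, with 33.1% in HS and 31.4% in HR. They correlated with other xenografts at r = 0.604 to 0.667 across probe sets, which are not independent replicates, against 0.732 to 0.834 among the other 6 xenografts. CreX, a bacteriophage RNA added to each hybridisation as a control, read 53 in HS and -423 in HR on LAPC9 for its 3' probe set and at least 68008 on the other 12 arrays. The LUCaP41 HS array had 3' over 5' ratios of 9.04 for GAPDH and 10.6 for ACTB, a measure of RNA integrity, where the other 13 arrays reached 2.65 and 2.93. None of 5 quality measures differed between HR and HS past the threshold (exact sign-flip p from 0.172 to 0.922, adjusted p from 0.859 to 0.922).

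**Figure D1:**
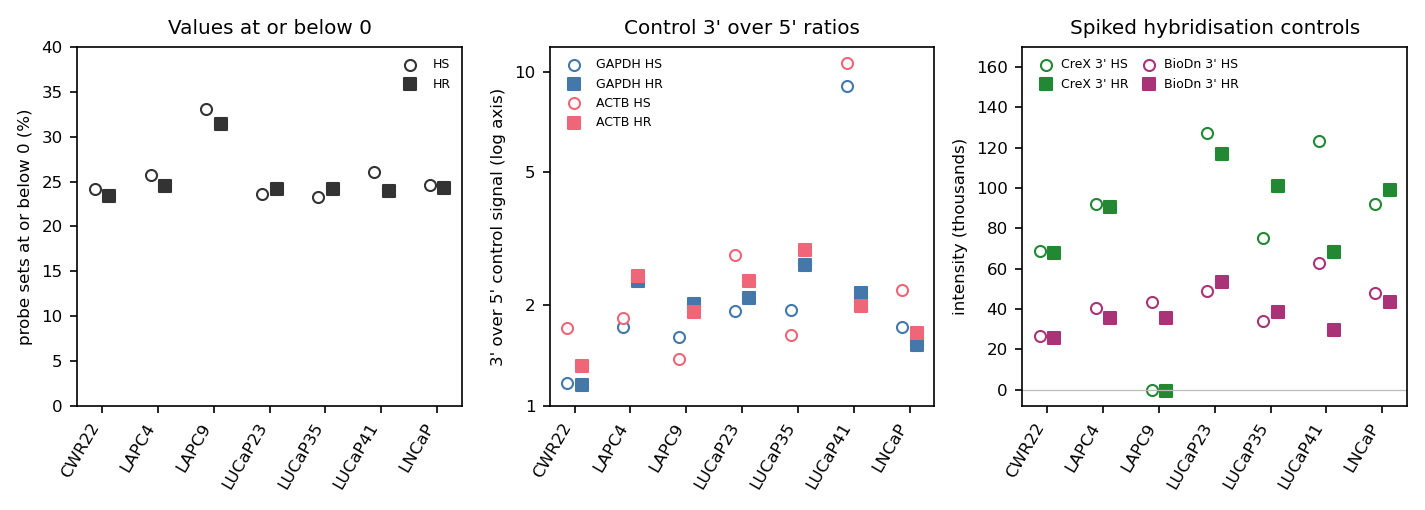
Quality of the 14 arrays, with 1 point per array, circles for HS and squares for HR. From left to right, the panels plot the percent of probe sets at or below 0, the 3' over 5' ratio of GAPDH and ACTB on a log axis, and the intensity of the spiked CreX and BioDn controls; LAPC9 has 33.1% and 31.4% of values at or below 0 and CreX near 0, and LUCaP41 HS has ratios of 9.04 and 10.6.

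Between HS and HR, no probe set with a gene name passed the test, so the genes given here are those with the smallest unadjusted p. The first on the HR side was LEPROT, a regulator of receptor trafficking transcribed from the leptin receptor locus, at 8.36 ± 0.39 in HS and 10.37 ± 0.99 in HR on the log2 scale (SD, n = 7 each). The difference was 2.01 ± 0.37 (SE), positive in 7 of 7 pairs, with 5 HS arrays at the floor, while the other tested LEPROT probe set stood at 0.12. On the HS side, with all arrays above the floor, were CD8B, a T cell co-receptor chain, at -1.35 ± 0.37, GDF15, a secreted stress cytokine, at -1.25 ± 0.36, and MYBPC1, a myosin-binding protein, at -1.14 ± 0.24, each negative in 7 of 7 pairs. Limma gave an adjusted p of 0.536 for LEPROT and 0.996 for CD8B, GDF15 and MYBPC1.

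Also on the HR side were the interleukin-1 receptor antagonist IL1RN at 1.58, the clathrin light chain CLTB at 1.65, the secreted guidance factor SEMA3C at 1.21 and the growth factor receptor PDGFRA at 1.38. The kinase MAPK7 stood at 1.01, the neuropeptide VIP at 1.36 and the small GTPase RHOC at 0.50. IL1RN, MAPK7 and VIP were positive in 7 of 7 pairs, although 4 HS arrays for IL1RN, 5 for CLTB, 4 for VIP, 2 for MAPK7 and 2 for PDGFRA lay at the floor. Also on the HS side were the calcineurin subunit PPP3CA at -1.60, the adaptor protein subunit AP3D1 at -1.86, the nuclear pore assembly factor AHCTF1 at -1.54, the transcription factor TBR1 at -1.40 and KANK3, of a family of actin regulators, at -1.19. PPP3CA, TBR1 and KANK3 were negative in 7 of 7 pairs, and 2 HR arrays for PPP3CA, 2 for AP3D1, 3 for AHCTF1, 3 for TBR1 and 1 for KANK3 lay at the floor. All of these had an adjusted p of 0.996. CLTB, PDGFRA and VIP each had another tested probe set with a difference of opposite sign, and the other AP3D1 probe set stood at -0.0069. With a floor at the 50th percentile, LEPROT stood at 0.72, IL1RN at 0.33, CLTB at 0.58, PDGFRA at 0.87, MAPK7 at 0.23, VIP at 0.41, PPP3CA at -1.02, AP3D1 at -1.17, AHCTF1 at -0.80 and TBR1 at -0.48.

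Of 9419 probe sets, 1 passed the threshold, higher in HR, and 0 passed lower. It has no gene in the probe table used. Its log2 difference was 1.58 ± 0.14 (SE), or 2.98-fold, with an adjusted p of 0.00186 in limma, and it was positive in 7 of 7 pairs. At an unadjusted p under 0.05 limma gave 316 probe sets, 141 higher and 175 lower, where 470.95 would fall by chance. Single pairs moved further, and the percent of probe sets that differed at least 2-fold ran from 19.2% in LUCaP23 to 44.3% in LAPC9. In LAPC9 these were 2029 higher and 2147 lower, of which 839 and 1123 were above the floor on both arrays, and in LUCaP23 978 and 828, of which 561 and 445 were. The count became 0 without the xenograft block, where the smallest adjusted p was 0.999945, without the variance trend, where it was 0.115, and without LAPC9 and LUCaP41 together, where it was 0.0557. Over all alternatives the adjusted p of the probe set in limma ran from 0.000200 to 0.999945, the highest without the block. Its log2 difference ran from 1.52 to 1.62 over these alternatives and from 1.38 to 1.71 over the 7 pairs.

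**Figure D2:**
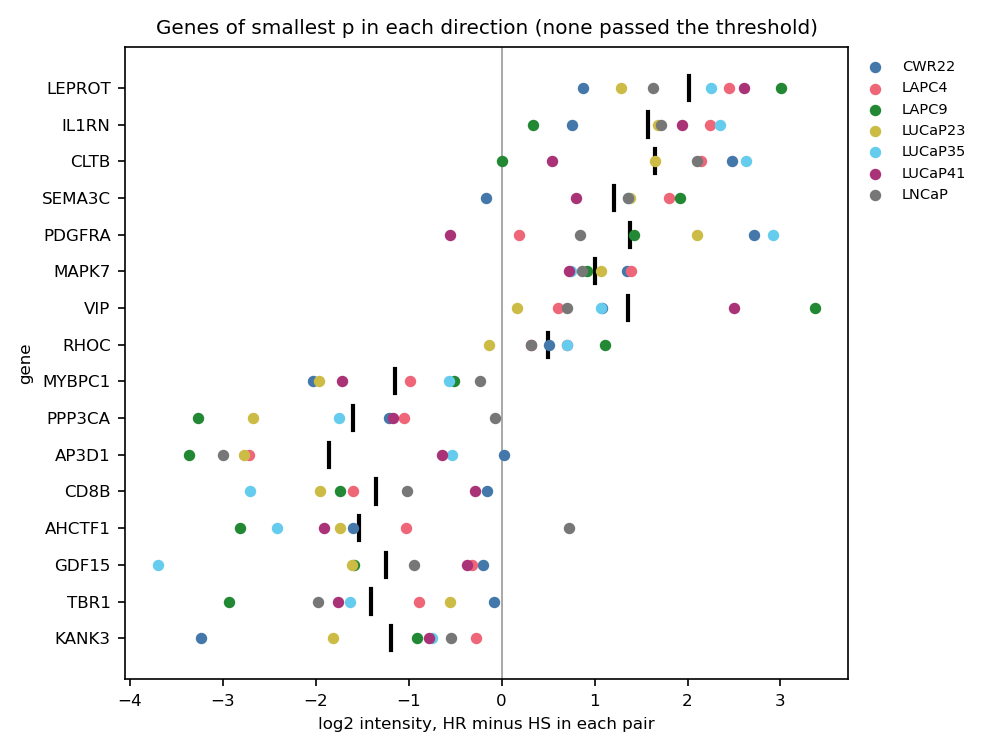
Differences of named genes between HR and HS, in log2 units, with 1 point per xenograft pair and a bar for the mean. LEPROT lies at a mean of 2.01 and AP3D1 at -1.86, and none of the genes passed the adjusted threshold.

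The count of probe sets that moved the same way in all 7 pairs by at least 1.2-fold asked the same question without a variance model. It gave 11, with 5 higher and 6 lower in HR, and 8 of them carried 1 gene name. Other ways of swapping HR and HS within pairs gave a median of 12, so a count of this size is what chance gives. LEPROT, IL1RN and MAPK7 were higher in every pair, and KANK3 was lower in every pair. The other 4 fall outside the rule for named genes and were chosen after their values were seen. They were ENDOD1, an endonuclease-domain protein, at -1.35, the actin-bundling protein FSCN1 at -1.17, the aldo-keto reductase AKR1B10 at -1.02 and the growth hormone gene GH1 at -0.95. With no minimum size the count was 91, with 37 higher and 54 lower. At least 1.5-fold in each pair left 3, and leaving out 1 pair gave 22 to 44.

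Genes regulated by androgen stood on average slightly lower in HR than in HS, and so did genes of hypoxia and glycolysis, but neither list passed after adjustment. Over 32 androgen response genes the mean log2 difference was -0.19 ± 0.15 (SD over 7 pairs), with 23 genes negative and 9 positive and 6 of 7 pairs lower. Over 33 hypoxia and glycolysis genes it was -0.36 ± 0.47 (SD over 7 pairs), with 29 genes negative and 4 positive and 5 of 7 pairs lower. Fry of limma gave an adjusted p of 0.204 for androgen response (unadjusted 0.00848) and 0.639 for hypoxia and glycolysis (unadjusted 0.0532). With 0 of 24 lists past the threshold in fry, 1 had an unadjusted p under 0.05. By the exact sign-flip test of the 7 pair means, androgen response had p = 0.0469 and an adjusted p of 0.75. As sign flips give no p below 0.0156, 1 list alone could not pass after adjustment over 24 lists.

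Within the androgen response list, the prostate-specific antigen gene KLK3 had a mean log2 difference of -0.97 ± 0.54 (SE), with 5 of 7 pairs lower. Its CWR22 pair stood at -5.14, and without CWR22 the mean was -0.28. The related kallikrein KLK2 was at -0.53, the membrane protease TMPRSS2 at -1.33, the immunophilin FKBP5 at -0.31, the retinal dehydrogenase ALDH1A3 at -0.74 and the stress-induced NDRG1 at -0.51. Without CWR22, TMPRSS2 stood at -0.78 and KLK2 at -0.25, and without LUCaP35 NDRG1 stood at -0.25. FKBP5 was higher in 3 pairs and lower in 3, and stood at 0.11 without LUCaP35 and 0.015 without LUCaP41. The polyamine-acetylating enzyme SAT1, also on the list, was at 0.43. Of the 32 members 0 passed in limma over all probe sets, 0 passed when adjusted over the list alone, and 3 had an unadjusted p under 0.05.

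In the hypoxia and glycolysis list, 9 genes were lower and 0 higher in HR at an unadjusted p under 0.05 in limma, and 0 passed, also when adjusted over the list alone. The glycolytic enzymes LDHA at -0.63 ± 0.21 (SE) and ALDOA at -0.50 ± 0.16 were lower in 7 of 7 pairs. The collagen-modifying PLOD2 at -1.08 ± 0.33 and the glycolytic GPI at -0.45 ± 0.15 were lower in 6 of 7 pairs. The mixed p of fry was 0.0460 (adjusted 0.945). Camera with a preset correlation placed this list past the threshold (adjusted p = 1.84e-08) as the 1 list it called. The correlation between its genes was estimated at 0.218, above the preset. With that estimate in camera the list had an adjusted p of 0.957. Its LUCaP35 pair stood at -1.32, and without LUCaP35 the mean was -0.19.

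The lists of markers of other cell types did not pass, with adjusted p values of 0.934 in fry. Being lists of human genes, they leave the amount of mouse host cells unmeasured. Endothelial markers averaged -0.12, where VWF, the clotting factor stored in vessel walls, was at -1.21 with 1 HS and 5 HR arrays at the floor, the growth factor receptor FLT1 at -1.02 and the nitric oxide synthase NOS3 at 1.11, or 0.70 without LUCaP41. Of 11 endothelial genes 5 were positive and 6 negative, and without CWR22 the list averaged -0.043. Erythroid and plasma proteins averaged -0.27, or -0.17 without LAPC4, with ALAS2, an enzyme of heme synthesis, at -0.45 and the globin HBB at -0.75. HBB was higher in HR in 4 of 7 pairs, and without LUCaP23 it stood at -0.29. Limma passed 0 members of the endothelial and erythroid lists, with VWF and FLT1 the 2 endothelial genes, and 0 erythroid genes, at an unadjusted p under 0.05.

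Steroid synthesis and inactivation genes averaged -0.17, or -0.26 without LUCaP23, with 8 positive and 13 negative. CYP17A1, the enzyme that opens androgen synthesis, was at -0.67 with 3 HS and 4 HR arrays at the floor, and at -0.29 without LAPC4. The estrogen hydroxylase CYP1B1 was at -1.34 with 2 HS and 3 HR arrays at the floor, and at -0.82 without LUCaP41. Steroid receptor cofactors and chaperones averaged -0.08, from -0.041 without LUCaP35 to -0.13 without LAPC9, with 13 positive and 24 negative, among them the acetyltransferase EP300 at -0.997, the coactivator NCOA6 at 0.46, the chaperone HSP90AB1 at 0.29 and the deacetylase HDAC1 at -0.30, lower in 7 of 7 pairs. HDAC1 had another probe set of opposite sign and stood at -0.16 without CWR22, and EP300 stood at -0.47 without LAPC4. Cell cycle genes averaged -0.11, or 0.027 without LUCaP35, with 19 positive and 32 negative, among them the kinetochore protein CENPF at -0.91, the mitotic motor KIF11 at -0.64, the ribonucleotide reductase RRM1 at -0.33 and the kinase CDK2 at -0.29. CENPF stood at -0.56 and KIF11 at -0.41 without LAPC9, and CDK2 at -0.17 without LUCaP41. Interferon response genes averaged -0.10, or 0.087 without LUCaP35 and -0.24 without LAPC9, with 11 positive and 19 negative, among them the regulator IRF7 at -0.77 and lower in 7 of 7 pairs, and the membrane protein IFITM1 at -0.94. These 4 lists had an adjusted p of 0.934 in fry.

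Growth factor genes had differences of both signs, with FGF8 at 2.08 and 6 HS arrays at the floor, IGF1 at -1.46 and the receptor FGFR4 at -0.69. The cell cycle inhibitor CDKN1C stood at -0.67, the mitochondrial death protein BNIP3 at -0.63, or -0.40 without LUCaP35, and the immediate early factor FOS at -0.59. The nuclear receptors RXRA and NR5A1 stood at 0.31 and 0.71. IGF1 and CDKN1C each had another probe set of opposite sign. The remaining 16 lists, growth signalling, other nuclear receptors, cholesterol and fatty acid synthesis, ribosomal proteins, oxidative phosphorylation, heat shock, apoptosis, immediate early genes, polyamines, WNT and hedgehog signalling and the luminal, basal, neuroendocrine, fibroblast, leukocyte and muscle markers, had means from -0.06 to 0.07. Their unadjusted p values in fry ran from 0.335 to 0.934.

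**Figure D3:**
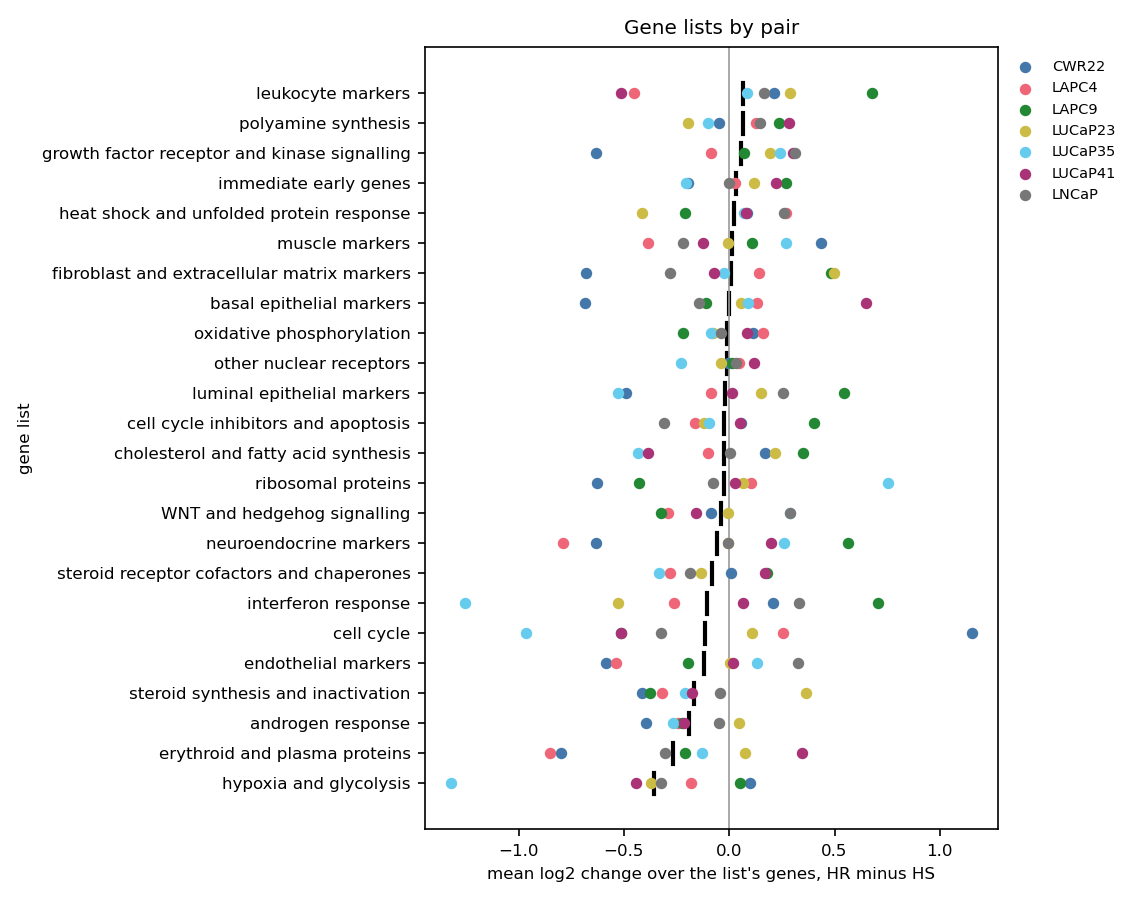
Mean log2 difference between HR and HS of each gene list, with 1 point per xenograft pair and a bar for the mean over the pairs. Androgen response averages -0.19 and hypoxia and glycolysis -0.36, the latter with LUCaP35 at -1.32, and 0 of 24 lists passed in fry.

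Arrays of different xenografts differed far more than HR differed from HS, by levels that the HS and HR arrays of a line shared. The labels do not say which arrays were hybridised together. Differences between lines can therefore not be told apart from a hybridisation shared by both arrays of a line. PSCA, a prostate stem cell antigen on the cell surface, averaged 17.63 ± 0.27 on the log2 scale in LAPC9 and 15.65 ± 0.25 in LUCaP41, against 11.59 ± 0.61 in LNCaP (SD, 2 arrays each). The range was 65.8-fold with LAPC9, whose arrays stood apart in quality, and is smaller without it, with LUCaP41 then the highest. LGALS3BP, a secreted ligand of galectin, stood at 15.57 ± 0.14 in LUCaP23 and 15.14 ± 0.62 in LUCaP35 and at the floor on the other 10 arrays. The galectin LGALS3 itself was above the floor in LUCaP41 at 14.02 ± 0.39, LAPC4 at 13.24 ± 0.26 and LUCaP23 at 13.05 ± 0.54. GSTP1, a glutathione transferase, was highest in LAPC4 at 14.23 ± 0.03 and LUCaP23 at 13.13 ± 0.52 and at the floor on the other 10 arrays, while its other probe set also read 12.65 ± 0.83 in LAPC9 and 10.68 ± 1.67 in LNCaP. The adjusted p of the moderated F in limma was 4.39e-05 for PSCA, 5.23e-05 for LGALS3BP, 0.000167 for LGALS3 and 0.000330 for GSTP1.

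The other 6 of the 10 genes with the largest F had 1 xenograft at or near the floor. The mucin MUC5AC, the small heat shock protein HSPB1, the receptor regulator LRIG1 and LRRC14 lay at the floor on both LAPC9 arrays, while the transcription factor MXI1 averaged 8.56 there and at least 12.23 in the others. The glutamate dehydrogenase GLUD1 lay at the floor on both LUCaP41 arrays. Without LAPC9 the adjusted p of the F in limma was 0.445 for MUC5AC, 0.271 for HSPB1 and 0.376 for LRRC14, and without LUCaP41 it was 0.168 for GLUD1. LRIG1 and MXI1 still passed without LAPC9, with F of 18.4 and 11.7, but not without LAPC9 and LUCaP41, and among the other xenografts LRIG1 ran from 11.87 in CWR22 to 15.31 in LUCaP41. Over all alternatives the adjusted p ran from 3.04e-05 to 0.445 for MUC5AC, from 5.51e-06 to 0.367 for HSPB1, from 5.75e-05 to 0.376 for LRRC14, from 4.21e-05 to 0.212 for GLUD1, from 3.08e-05 to 0.0620 for LRIG1 and from 0.000144 to 0.153 for MXI1. Of 2 tested probe sets each for LRIG1 and GLUD1, 1 passed, and of 3 for MXI1, 2 passed.

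In limma 1538 probe sets, or 16.3%, passed the threshold of the F over xenografts, against 1 for HR versus HS. Xenograft held 65.9% of the summed squares after the floor, where its share of the degrees of freedom was 46.2%, and the state held 4.68%, where that share was 7.69%. Of genes, 16.4% passed, and by Fisher's exact test the share was higher for basal epithelial markers at 50%, androgen response at 43.8%, luminal epithelial markers at 40.9%, heat shock at 40.6% and oxidative phosphorylation at 39.2%. It was lower for the cell cycle at 3.92% and for fibroblast markers, where 0 of 28 genes passed in limma and 4 had an unadjusted p under 0.05. The adjusted p of these 7 shares ran from 0.00188 to 0.0418. Fisher's test takes genes as independent units, which genes of 1 list measured on the same arrays are not, so these values do not measure the spread over tumours. The count of probe sets was 729 without LAPC9, 949 without LUCaP23 and 357 without LAPC9 and LUCaP41, and without LAPC9 none of the 7 list shares passed, with adjusted p from 0.0583 to 0.329, where all alternatives gave 1.83e-05 to 1.

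**Figure D4:**
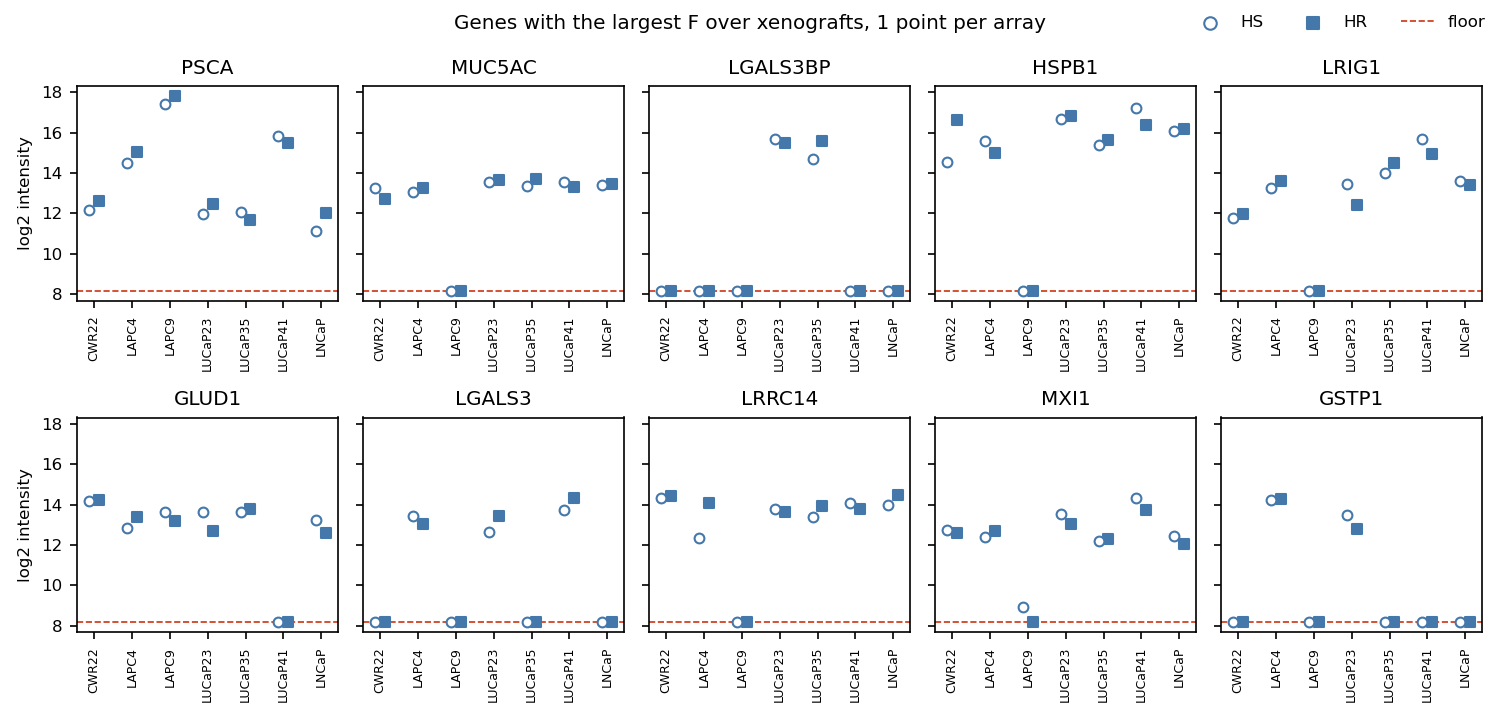
Log2 intensity of the 10 genes with the largest F over xenografts, with 1 point per array, circles for HS, squares for HR and a dashed line at the floor of 8.17. PSCA spans 11.59 in LNCaP to 17.63 in LAPC9, and MUC5AC, HSPB1, LRIG1 and LRRC14 lie at the floor on both LAPC9 arrays.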

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

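The tests of the CreX controls and of the 7 other controls alone were chosen after the values of the LAPC9 arrays were seen. A value was taken up here when its gap to the nearest of the other 6 values of its group was a larger part of the group's range than Dixon's critical value allows. Chance marks about 1 in 20 groups, and 13 of 90 groups held such a value, 6 of 10 for array measures, 5 of 56 for genes and 2 of 24 for gene lists.

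The LAPC9 arrays had medians of 1216.5 in HS and 1130 in HR, above 781.5 to 925 on the other 12, and 33.1% and 31.4% of probe sets at or below 0, against 23.3% to 26.1%. Degraded RNA would have raised the 3' over 5' ratios, and these reached 2.01 on LAPC9 against 10.6 elsewhere, while a separate hybridisation or another control mixture is a candidate explanation, since the highest CreX value on LAPC9 was 53 and the lowest on the other 12 arrays was 46322. Weak hybridisation scaled up afterwards would have raised the controls. Their median was 0.385 of that on the other arrays, which met the bound set beforehand as speaking against it, and 0.447 without CreX. It stays open, since the 7 other controls ran singly from 0.0347 to 3.17 of their level elsewhere. On both LAPC9 arrays BioB-M lay above all other arrays, the 5' BioDn lay below them and 3 controls lay within their range. The amounts added also cannot be taken as equal where CreX is missing. A wrong label stays open too, since the deviations of the LAPC9 arrays over bright probe sets correlated at r = 0.602 across probe sets, against at most 0.126 with any other xenograft, and a shared hybridisation would also make them alike. LAPC9 biology cannot account for a control added to the sample, but for tumour genes such as HSPB1 it stays open and was not tested.

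The LUCaP41 HS array had 3' over 5' ratios of 9.04 for GAPDH and 10.6 for ACTB, where the other HS arrays reached 1.93 and 2.83. In the LUCaP35 pair, GDF15 stood at -3.70 on the log2 scale, against -1.61 to -0.20 in the other 6 pairs. NDRG1 stood at -2.11 in LUCaP35, against -0.70 to 0.10. KLK3 stood at -5.14 in CWR22, against -0.82 to 0.64. EP300 stood at -4.18 in LAPC4, against -1.34 to 0.17. HDAC1 stood at -1.11 in CWR22, against -0.29 to -0.04. The growth factor receptor and kinase signalling list averaged -0.63 in CWR22, against -0.09 to 0.31. The hypoxia and glycolysis list averaged -1.32 in LUCaP35, against -0.44 to 0.10.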

How the results depend on the processing

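Floors at the 30th and 50th percentile and leaving out LAPC9 and LUCaP41 together were chosen after seeing the data. The count of 1 probe set for HR versus HS held in 17 of 20 settings; it was 0 without the xenograft block, without the variance trend and without LAPC9 and LUCaP41, the last with fewer pairs. No list passed in 21 of 22 settings, and camera with a preset correlation called 1. The count moved the same way in all pairs, 11, was 6 with a filter at the 50th percentile (fewer probe sets tested), 5 with a floor there, 91 with no minimum, 3 at 1.5-fold, and, with fewer pairs to satisfy, 77 without LAPC9 and LUCaP41 and 22 to 44 leaving out 1 pair. The xenograft count, 1538, was 729 to 1457 leaving out 1 xenograft (729 without LAPC9, 949 without LUCaP23) and 357 without LAPC9 and LUCaP41. FKBP5, at -0.31, turned to 0.044 with a floor at the 50th percentile, 0.015 without LUCaP41 and 0.018 without it and LAPC9, and ranged from -0.80 without CWR22 to 0.11 without LUCaP35. Cofactors and chaperones turned to 0.00082 and endothelial markers to 0.091 with a filter at the 50th percentile, and the cell cycle to 0.046 without LAPC9 and LUCaP41. Leaving out 1 pair, the cell cycle ranged from -0.32 to 0.027 and interferon response from -0.24 to 0.087, both highest without LUCaP35. Where no construction is given, the cause was not tested. Of 1072 gene differences under other settings, 1065 kept direction and side of the threshold, as did 154 of 159 list means. For genes and lists these counts do not measure robustness. No named gene passed for HR versus HS and no list did in fry, so few could change sides. Genes were also mostly chosen by small p or by moving the same way in most pairs, which favours a kept direction. Direction and side were also kept by 170 of 180 xenograft F values and 71 of 126 list shares. Among values not given in the report, a floor at the 50th percentile moved VWF to -0.30, EP300 to -0.36, CENPF to -0.36, CYP17A1 to -0.42, IFITM1 to -0.46, FSCN1 to -0.49, AKR1B10 to -0.50, IGF1 to -0.93, FGF8 to 1.38 and the steroid synthesis list to -0.06. Leaving out LAPC9 and LUCaP41 moved KIF11 to -0.11, CDK2 to -0.15, CENPF to -0.24, ALAS2 to -0.26, KLK2 to -0.28, FOS to -0.36, FLT1 to -0.40, ALDH1A3 to -0.46, GH1 to -0.61, HBB to -1.44, NCOA6 to 0.28, NOS3 to 0.38, NR5A1 to 0.42, VIP to 0.73, the erythroid list to -0.40, the cofactor list to -0.16 and the interferon list to -0.30. Array weights moved KLK2 to -0.25, FLT1 to -0.60, HBB to -1.35, the interferon list to -0.22, the endothelial list to -0.062 and the steroid synthesis list to -0.085. Each of the 16 lists given as a range turned sign in at least 1 setting. The median difference of all probe sets was -0.0087 as deposited, 0.0030 with quantile normalization and -0.0034 with median scaling. The 10th and 20th percentile floors could not be run. Signal over background limits genes near the floor, where 35% of values lay.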

Other observations

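The tests of the luminal genes, of the list counts over other splits and of the HR count without LAPC9 were chosen after the results were seen.

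Single pairs moved in directions of their own that the means over 7 pairs do not show. Cell cycle genes averaged 1.15 higher in HR in CWR22 on the log2 scale and stood at -0.96 in LUCaP35, -0.51 in LAPC9 and -0.51 in LUCaP41. Interferon response genes averaged -1.25 in LUCaP35, -0.53 in LUCaP23 and 0.71 in LAPC9. Erythroid and plasma protein genes averaged -0.85 in LAPC4 and -0.80 in CWR22, and endothelial markers -0.54 and -0.59 in the same pairs. With 1 array per xenograft and state, none of these differences between pairs was tested.

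Several genes that read high in the other 6 xenografts read at background on both LAPC9 arrays. Of 1852 probe sets above 2502 on all 12 other arrays, 10 lay at or below the floor on both LAPC9 arrays, 1 of 1697 did so for LUCaP41, and 0 did for the other 5 xenografts. The 8 with a gene name were HSPB1, LRRC14, LRIG1, DNAJB12, MUC5AC, CHERP, ACADS and PLK1, and those not among the 10 genes with the largest F were chosen after their values were seen. HSPB1 was at least 23755 on the other arrays and read -891 and -3686 on LAPC9. PLK1, a mitotic kinase, was at least 2760 elsewhere and read -4309 and -2117. DNAJB12, a chaperone of the endoplasmic reticulum, read -27939 and -28573, far below background, against at least 5872 elsewhere. In the other direction, GUCA2B and ADGRB1 were above 2502 on both LAPC9 arrays and at or below the floor on the other 12, also chosen after their values were seen.

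Swapping HR and HS within pairs gives 64 splits. Only the real one had a probe set past the threshold, with 1 against at most 0 in the others, which by the splits makes chance unlikely for that count. It does not exclude chance, since 1 of 64 is the smallest share the splits can give and the count is 0 in 3 of the 20 other settings. At an unadjusted p under 0.05, 62 of 64 splits gave at least the real 316 and the highest other gave 528, so chance cannot be excluded there. Without LAPC9 the count was also 1, below the 10 or more taken as the sign that noise of the LAPC9 arrays hid changes. Leaving out a pair also lowers the power to find changes, so this count does not decide whether such noise hid any. For probe sets that moved the same way in all pairs, 44 of the 64 splits gave at least the real 11, and the highest other gave 22, so chance cannot be excluded. For lists past the threshold, 64 of 64 gave at least the real 0, which a count of 0 makes certain, so the splits decide nothing there; the highest other gave 1. For differences between xenografts, 1 of 100 pairings of HS with HR arrays gave as many, with 1538 in the real pairing and at most 121 in the others. A hybridisation shared by both arrays of a line would raise the real count too, so the pairings do not separate it from the line.

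Androgen response genes averaged lower in HR by a small amount, -0.19, which did not pass after adjustment over 24 lists. By exact sign flips of the 7 pair means p was 0.0469, under the bound of 0.05 set beforehand for this test. The value adjusted over the lists was 0.75, but it decides nothing, since flips give no p below 0.0156 and 1 list alone could not pass. The adjusted p in fry was 0.204, so chance cannot be excluded. Leaving out 1 pair, the mean ran from -0.23 to -0.16. The unadjusted p in fry ran from 0.00277 without LUCaP23 to 0.0586 without LUCaP41, where the mean was -0.19. The rule set beforehand, that 1 pair decides where this p rises above 0.05 without some pair, was therefore met. With all 7 pairs the fry p was also 0.0536 with array weights and 0.463 without the block, so LUCaP41 is not alone in moving its side of 0.05. A lower share of epithelial cells would lower luminal genes too. Those outside the androgen list did not fall on average, at 0.042 ± 0.38 (SD over 7 pairs), with 3 pairs higher and 4 lower. Their difference from the androgen list had an exact sign-flip p of 0.109. With this spread over pairs, a contribution of that share is not excluded. The change of hormone state named by the labels stays open and was not tested apart from these.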
